A study of Mus musculus with 9 samples.

How the data were processed

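Gastrocnemius muscle was sequenced from C57BL/6J mice aged 8 to 10 weeks that carried an osmotic minipump, a small implanted capsule that releases its content at a constant rate. Per the labels' protocols the pump released ammonium acetate at 2.5 mmol per kg per day or phosphate-buffered saline (PBS), and the muscle was collected 4 weeks after implantation. RNA was extracted with a column kit and sequenced on an Illumina instrument, per the labels' protocols. The labels place 4 libraries in the PBS group (numbers 4, 5, 7 and 8) and 5 in the ammonium acetate group (numbers 4 to 8). They do not state that each library is a separate animal, so p-values measure the spread between these libraries. The sex of the mice, the library type and its strand setting are not given in the sources used here.

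The authors deposited a single table of FPKM values (fragments scaled by gene length and by the total of counted fragments) for 35275 genes with Ensembl identifiers, symbols, coordinates and gene lengths. The submitters' processing notes name STAR, TopHat, HTSeq, DESeq2 and the mm10 build, with no versions and no roles. Whether fragments matching several genes were counted is not given in the sources used here, so values of near-identical genes such as the globin paralogs are uncertain. Of the identifiers, 97.8% were found in GENCODE M21, which is on the same build (GRCm38), and 99.9% of these overlapped the listed position on the same chromosome. Coordinates are those of the deposited table. In each library FPKM times gene length in kb summed to the same total, and 100.0% of the values above 0 corresponded to whole reads within 0.05 read. The libraries held from 24930547 to 41780251 reads recovered in this way. An FPKM of 0.0295 in the PBS library 4 stands for 1 read on a gene of 1 kb. No pair of libraries held identical values.

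Genes with a mean FPKM of at least 0.5 over the 9 libraries were tested, which kept 11337. The test was limma (version 3.58.1 in R 4.3.3) with a mean-variance trend on log2(FPKM + 0.5), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of genes of low FPKM. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 44 lists with at least 3 tested genes. The same lists were tested with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Composition was compared over 18 measures by exact two-sided permutation of all 126 splits of the 9 libraries, which gives no p below 0.00794. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

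The gene test, the list test, the 45 lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule named the 10 genes of largest change in each direction among those past the threshold, filled with the genes of smallest unadjusted p where there were fewer. Predicted or unnamed genes were skipped. It also named 16 genes fixed from earlier work on muscle hyperammonaemia and the 3 members of smallest p in each list described. The values of 1 gene that the rule names are not reported here. The 25 lists described with examples were picked after all list results had been seen, as the 16 past the threshold and 9 tied to the study. That choice also set which genes were screened for outlying libraries. A further 5 lists were drawn up after the leading genes had been seen, 1 of them (giant genes) with a gene length trend in mind, so 50 lists were run in all.

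The gene and list counts were each recomputed under 26 alternatives. They covered the pseudocount, the filter, 3 other scalings, the moderation of the variance and library weights. They also covered the threshold of the gene test, the replicate number as a block and each library left out in turn. Of the 26, 4 were chosen after seeing the data, namely ammonium acetate libraries 6 and 8 left out together, each library's trend on gene length or on transcript GC content removed (lowess, span 0.3), and limma's voom on the recovered reads. The gene and list counts were also compared over 100 of the 126 splits of the libraries, namely the real grouping and others drawn at random. The technical measures of each library were also chosen after seeing the data.

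The gene test was tested on simulated data with the means and spreads of the 11337 genes. At an adjusted p of 0.05 it recovered 42.6% of genes changed 1.5-fold, 80.0% of those changed 2-fold and 98.4% of those changed 4-fold over 10 rounds, with 102 false calls over all rounds. Of 30 simulated lists shifted by 0.3 on the log2 scale, 30 were called, and 1 of 410 other lists was called. These simulated genes varied independently of each other, which real genes of a list do not. Each size of change was planted in 500 genes over the 10 rounds, and many changed genes ease the adjustment. The shares recovered therefore do not tell how many changed genes the real comparison would miss.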

Results

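Skeletal muscle takes up ammonia when the liver does not clear it, and the series was designed to describe the response of muscle to such a load. Gene expression was measured by RNA sequencing in gastrocnemius, the large calf muscle, of mice that received ammonium acetate from an implanted pump for 4 weeks (5 libraries) or PBS (4 libraries). The values were FPKM as the authors deposited them. The reads behind them amounted to 33664748 ± 6668617 in PBS (SD, n = 4) and 31293852 ± 5570241 in ammonium acetate (SD, n = 5), and single libraries held between 24930547 and 41780251 reads. The design gives a single comparison, ammonium acetate against PBS.

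No gene passed the threshold between the groups. Ostn, which encodes the secreted muscle peptide musclin (ENSMUSG00000052276, chromosome 16, 27307489 to 27351212, mm10), had the smallest p. It measured 15.9 ± 2.90 FPKM in PBS (SD, n = 4) and 24.5 ± 2.08 in ammonium acetate (SD, n = 5), a log2 fold change of 0.63 with a standard error of 0.13. S100a9, a calcium-binding protein abundant in neutrophils (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), measured 0.594 ± 0.303 and 2.44 ± 1.29 FPKM. These values rested on 4 to 69 reads per library. The mitotic kinase Aurka measured 4.49 ± 0.392 and 7.34 ± 1.6 FPKM, and the histone variant H2afx 5.67 ± 0.912 and 8.27 ± 0.716. The other genes of smallest p with higher values in ammonium acetate were Mad2l2, Ccdc124, Hoxc11, AI462493, Slc15a4 and Nol12, with log2 fold changes from 0.34 for Slc15a4 to 0.57 for Mad2l2.

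Among the genes with lower values in ammonium acetate, the activity-induced transcription factor Fosb (ENSMUSG00000003545, chromosome 7, 19302721 to 19310045) measured 4.26 ± 3.24 FPKM in PBS and 0.937 ± 0.444 in ammonium acetate. Its log2 fold change was -1.57 with a standard error of 0.38. Igfn1, an immunoglobulin-like muscle protein, measured 2.95 ± 2.56 and 0.435 ± 0.259 FPKM, and its PBS values ranged from 1.14 to 6.61. The ADP-ribosyltransferase gene Art5 measured 11.5 ± 1.69 and 7.60 ± 1.14. The alpha globin gene Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) measured 78.8 ± 12.1 and 54.6 ± 8.69 FPKM, and its reads may be shared with Hba-a2. Osr2, Klf11, Sp100, the collagen receptor subunit Itga11, Arrdc3 and Amotl2 had log2 fold changes from -0.84 for Itga11 to -0.54 for Klf11. In each of these 20 genes the 5 ammonium acetate libraries lay on 1 side of the PBS mean, which the choice by smallest p in the same libraries favours.

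By limma with Benjamini-Hochberg adjustment, 0 of 11337 genes passed 0.05 and the smallest adjusted p was 0.527. At an unadjusted p under 0.05 there were 972 genes, 364 higher and 608 lower, where 566.85 are expected by chance, and limma's voom on the recovered reads also gave 0 genes, with 924 unadjusted. The groups did not overlap at all in 241 genes, 2.13% of those tested, where chance gives 1.59%.

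**Figure D1:**
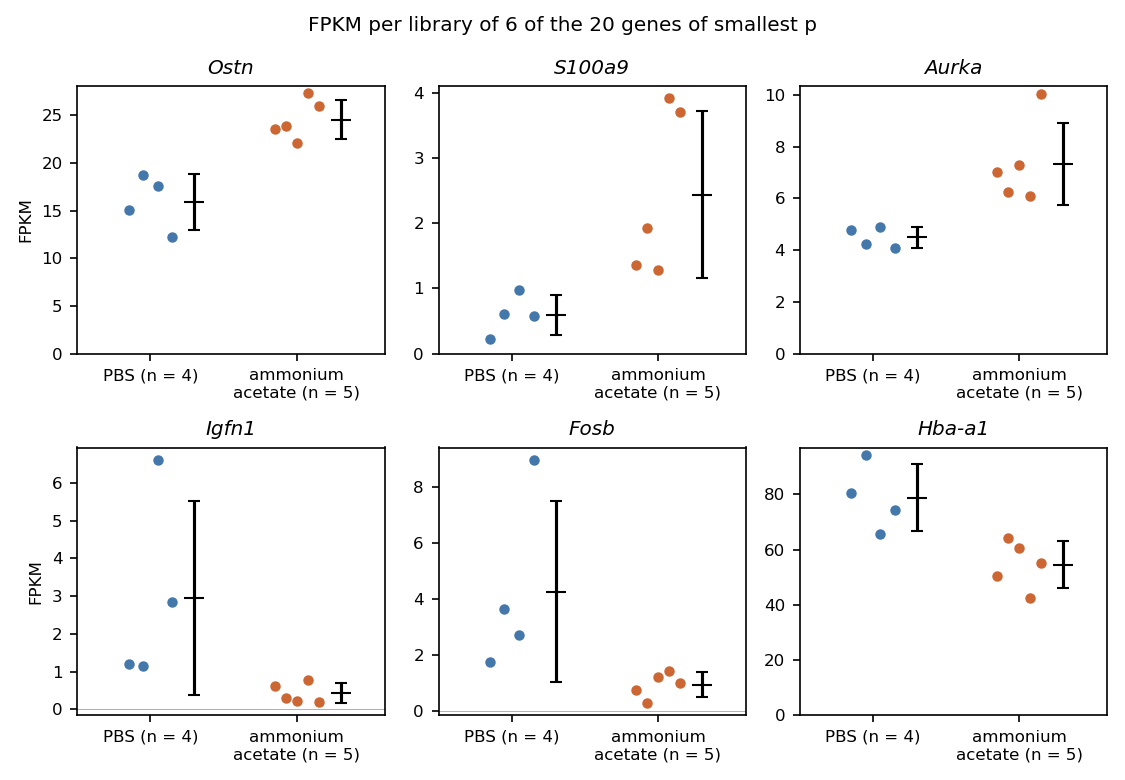
FPKM per library (vertical axis, from 0) in 4 PBS and 5 ammonium acetate libraries for 6 of the 20 genes of smallest p. Points are libraries, and the bar beside them is the mean ± SD. Ostn lay between 12.2 and 18.7 in PBS and between 22.1 and 27.3 in ammonium acetate, and none of the 6 genes passed the adjusted threshold.

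The 16 genes fixed from earlier work on muscle hyperammonaemia showed no difference past the threshold, either over all genes or adjusted over the list alone (0 of 16, smallest adjusted p 0.797). Mstn, which encodes myostatin, an inhibitor of muscle growth, measured 31.9 ± 9.13 FPKM in PBS and 39.9 ± 12.2 in ammonium acetate. Its log2 fold change was 0.29, with a 95% interval from -0.30 to 0.88. Ammonium acetate 7 stood at 19.2 FPKM, and the log2 fold change of Mstn was 0.53 without ammonium acetate replicate 7, 0.18 without ammonium acetate replicate 5 and 0.15 without PBS replicate 8. The stress-response transcription factor Atf4 measured 97.2 ± 3.82 and 111 ± 14.0 FPKM (log2 fold change 0.19, interval -0.04 to 0.41). Glul, the glutamine synthetase that binds ammonia into glutamine, measured 80.9 ± 18.2 and 71.6 ± 8.02 (-0.15, interval -0.48 to 0.17). The ubiquitin ligases of muscle atrophy Fbxo32 and Trim63 had log2 fold changes of -0.25 and 0.11. With each library's gene length trend removed these were -0.03 and 0.06. The log2 fold change of Atf4 was 0.07 without ammonium acetate 6 and 8. The cell cycle inhibitor Cdkn1a measured 15.5 ± 5.27 and 21.4 ± 16.1 FPKM, and its interval of -0.79 to 1.22 was the only 1 of the 16 to reach beyond a 2-fold change with all 9 libraries. The remaining 10 genes had log2 fold changes between -0.20 for Slc7a5 and 0.03 for Hif1a, with Ddit3 at -0.17, Ppargc1a at -0.16, Nfkb1 at -0.12, Sirt3 at -0.06, Glud1 at -0.04, Tfam at 0.02, Rela at -0.02 and Eif2ak4 at -0.00041.

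**Figure D2:**
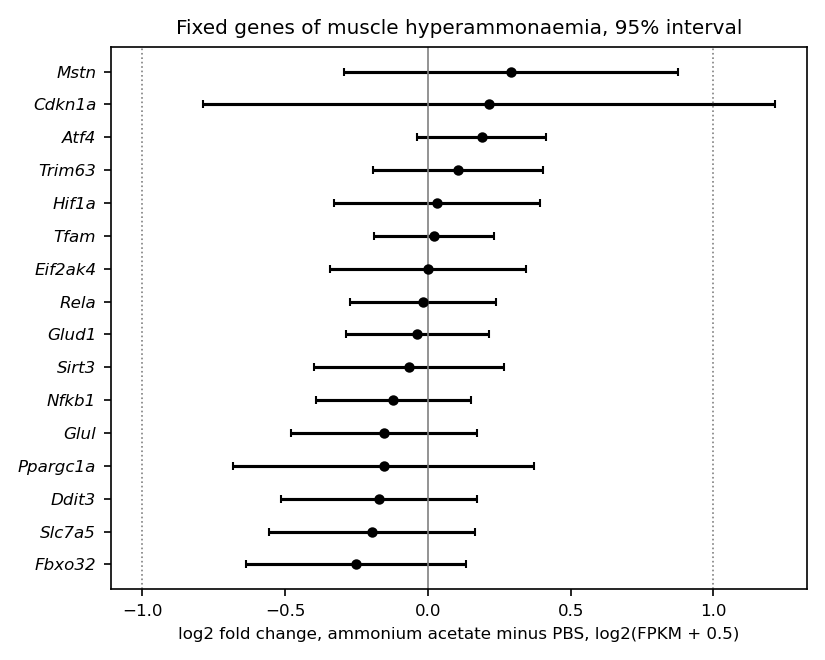
Log2 fold change, ammonium acetate minus PBS, on the log2(FPKM + 0.5) scale (horizontal axis) of the 16 fixed genes. Points are limma estimates over 4 PBS and 5 ammonium acetate libraries, bars the 95% interval, and dotted lines a 2-fold change. All 16 intervals include 0.

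Of the 44 lists tested, 16 passed 0.05 by camera with the preset correlation, 8 higher and 8 lower in ammonium acetate. None passed with an estimated correlation (smallest adjusted p = 0.854) and none by fry (smallest adjusted p = 0.580). The correlations estimated within these 16 lists were between 0.0876 and 0.995, far above the preset.

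Ribosomal proteins, proteasome subunits, nuclear-encoded respiratory complexes and antioxidant genes lay slightly higher in ammonium acetate as lists. Of the cytosolic ribosomal proteins, 43 of 44 were higher, with a median log2 fold change of 0.23 (camera adjusted p = 4.1e-11, and p = 0.204 with an estimated correlation). Rpl35 measured 10.6 ± 1.39 FPKM in PBS and 15.5 ± 3.89 in ammonium acetate, and Rps20 48.1 ± 7.77 and 64.2 ± 14.7. All 31 proteasome subunits were higher, with a median of 0.19 (adjusted p = 2.11e-08, p = 0.10 with an estimated correlation), among them Psmb5 at 110 ± 9.13 and 138 ± 23.1 FPKM. Of the mitochondrial ribosomal proteins 27 of 30 were higher, with a median of 0.18 (adjusted p = 9.59e-06, p = 0.237 with an estimated correlation), led by Mrps6 at 7.37 ± 1.22 and 11.1 ± 2.29. Nuclear genes of respiratory complex I were higher in 35 of 36 cases, median 0.17 (adjusted p = 6.01e-05, p = 0.356 with an estimated correlation), and those of complexes II to V in 36 of 41, median 0.11 (adjusted p = 0.00232, p = 0.493 with an estimated correlation). Ndufv3 measured 44.7 ± 7.98 and 53.2 ± 6.86 FPKM, and Cox8b 446 ± 103 and 549 ± 122. Sdha, the gene of complexes II to V with the smallest p, was on the other side at 332 ± 60.5 and 277 ± 59.6 (log2 fold change -0.27). The antioxidant list had 18 of 25 members higher, median 0.13 (adjusted p = 0.0152, p = 0.107 with an estimated correlation), with Gpx1, a glutathione peroxidase, at 53 ± 5.17 and 73.4 ± 18.4. No member of these 6 lists passed the threshold adjusted over the list alone. Median gene length ran from 932 to 1835 bases in the ribosomal, proteasome and respiratory lists, and was 2294 in the antioxidant list. Libraries 6 and 8 of ammonium acetate, described below with the gene length trend, had higher values of the shortest genes. Without these 2 libraries the medians were 0.03 for the cytosolic and 0.03 for the mitochondrial ribosomal proteins, 0.07 for the proteasome, -0.01 for complex I, -0.03 for complexes II to V and 0.12 for the antioxidant list. The proteasome (adjusted p = 0.000292) and antioxidant (adjusted p = 0.0192) lists then still passed, and the other 4 did not. With the gene length trend removed, complex I (median 0.05, adjusted p = 0.435), complexes II to V (0.02, adjusted p = 0.960) and the antioxidant list (0.08, adjusted p = 0.134) no longer passed, and the cytosolic ribosomal (0.10), mitochondrial ribosomal (0.09) and proteasome (0.08) lists passed with lower medians. Leaving out ammonium acetate 8 alone gave 0.14 for the cytosolic and 0.10 for the mitochondrial ribosomal proteins, 0.13 for the proteasome and 0.08 for complex I. For complex I the median was 0.09 without PBS 7 and 0.27 without ammonium acetate 4. The complexes II to V list did not pass without PBS 7 (median 0.02), ammonium acetate 6 (0.08) or ammonium acetate 8 (0.03), and its median was 0.17 without PBS 4, 0.19 without PBS 5, 0.20 without ammonium acetate 4 and 0.17 without ammonium acetate 5. The antioxidant list did not pass without PBS 7 (median 0.11, adjusted p = 0.0525), and its median was 0.09 without PBS 4 and 0.07 without ammonium acetate 7.

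Matrix genes and the markers of several cell types between the fibres lay lower in ammonium acetate. Of the extracellular matrix genes, 21 of 22 were lower, with a median log2 fold change of -0.48 (adjusted p = 3.93e-05, p = 0.236 with an estimated correlation). Fibronectin (Fn1) measured 11.7 ± 4.45 FPKM in PBS and 6.42 ± 2.56 in ammonium acetate, and Col6a1 16.8 ± 4.71 and 10.7 ± 4.19. All 11 endothelial markers were lower, median -0.38 (adjusted p = 0.000577, p = 0.133 with an estimated correlation), including Kdr, a receptor of vascular growth factor, at 11.8 ± 1.14 and 7.07 ± 3.19. All 10 markers of fibro-adipogenic progenitors, the connective tissue stem cells of muscle, were lower, median -0.24 (adjusted p = 0.0165, p = 0.297 with an estimated correlation), with Pdgfra at 3.62 ± 1.14 and 2.22 ± 0.715. Macrophage markers were lower in 11 of 11 cases, median -0.32 (adjusted p = 0.0217, p = 0.355 with an estimated correlation), with Csf1r at 3.73 ± 1.29 and 2.35 ± 0.616. Smooth muscle and pericyte markers were lower in 7 of 10, median -0.31 (adjusted p = 0.0474, p = 0.340 with an estimated correlation), with Myh11 at 5.53 ± 0.643 and 3.33 ± 1.88. No member of these 5 lists passed adjusted over the list alone. Without ammonium acetate 6 and 8, in which long genes had lower values, the medians were -0.16, -0.18, -0.12, -0.25 and -0.07 in this order, and the smooth muscle list no longer passed. With the gene length trend removed they were -0.29, -0.32, -0.31, -0.34 and -0.19 in the same order, and the 5 lists passed. The progenitor list did not pass without PBS 5 (median -0.15), and its median was -0.45 without PBS 4 and -0.16 without ammonium acetate 6. The macrophage list did not pass without PBS 5 (-0.19), PBS 7 (-0.24), PBS 8 (-0.22) or ammonium acetate 5 (-0.33), and its median was -0.58 without PBS 4. The smooth muscle list did not pass without PBS 4 (-0.35), PBS 5 (-0.29), ammonium acetate 6 (-0.24), 7 (-0.31) or 8 (-0.23), nor with the GC content trend removed (adjusted p = 0.0544). The endothelial median was -0.24 without ammonium acetate 6.

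Blood, interferon and activity genes were also among the lists past the preset-correlation threshold. All 5 erythroid genes were lower, median log2 fold change -0.41 (adjusted p = 0.000206, p = 0.0525 with an estimated correlation), and 5 of 5 passed adjusted over the list alone, against 0 over all genes. The beta globin gene Hbb-bs measured 96.8 ± 14.8 FPKM in PBS and 67.2 ± 14.0 in ammonium acetate, and Alas2, the first enzyme of haem synthesis in red cells, 2.58 ± 0.0816 and 1.87 ± 0.405. Of the 3 neutrophil markers tested, S100a8 (0.436 ± 0.160 and 1.32 ± 0.727 FPKM, on 3 to 32 reads) and S100a9 were higher and passed adjusted over the list alone, and Mmp9 was lower. The median was 0.88 (adjusted p = 0.0247, p = 0.0896 with an estimated correlation), and the list did not pass without PBS 4 (median 0.81) or ammonium acetate 4 (0.93). The interferon response list had 16 of 17 members lower, median -0.42 (adjusted p = 0.000216, p = 0.217 with an estimated correlation), and 0 members passed adjusted over the list alone. Gbp2, an interferon-induced GTPase, measured 8.59 ± 8.60 and 2.65 ± 0.529 FPKM, and without PBS 8 the list's median was -0.19 (adjusted p = 0.00874). Among members with a mean FPKM of at least 2 the list did not pass (median -0.18, adjusted p = 0.230). Of the immediate early genes, which respond within minutes to contraction and other stimuli, 13 of 16 were lower, median -0.39 (adjusted p = 0.0268, p = 0.348 with an estimated correlation). Fosb was the only 1 to pass adjusted over the list alone, Egr1 measured 9.37 ± 3.66 and 4.45 ± 3.25 FPKM, and Nr4a3 was on the other side at 2.26 ± 1.26 and 5.5 ± 2.89. The list did not pass without PBS 8 (median -0.23) or ammonium acetate 5 (-0.22). The skin list (6 of 6 higher, median 0.96, adjusted p = 0.0247, p = 0.302 with an estimated correlation) rested on ammonium acetate 5, where Krt5 stood at 19.3, Krt10 at 16.1 and Lor at 9.09 FPKM. Without that library fewer than 3 of its members reached the expression filter, so it was not tested. Without ammonium acetate 6 and 8 the medians were -0.55 for the erythroid, 0.70 for the neutrophil, -0.34 for the interferon, -0.35 for the immediate early and 1.6 for the skin list, and the 5 lists passed. With the gene length trend removed, the erythroid (median -0.56), interferon (-0.35) and immediate early (-0.40) lists passed, and the neutrophil (median 0.71, adjusted p = 0.0716) and skin (0.90, adjusted p = 0.0747) lists no longer passed, nor did the skin list with the GC content trend removed (0.99, adjusted p = 0.0774). These medians had moved little, so the lost calls do not show that the trends made the difference.

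**Figure D3:**
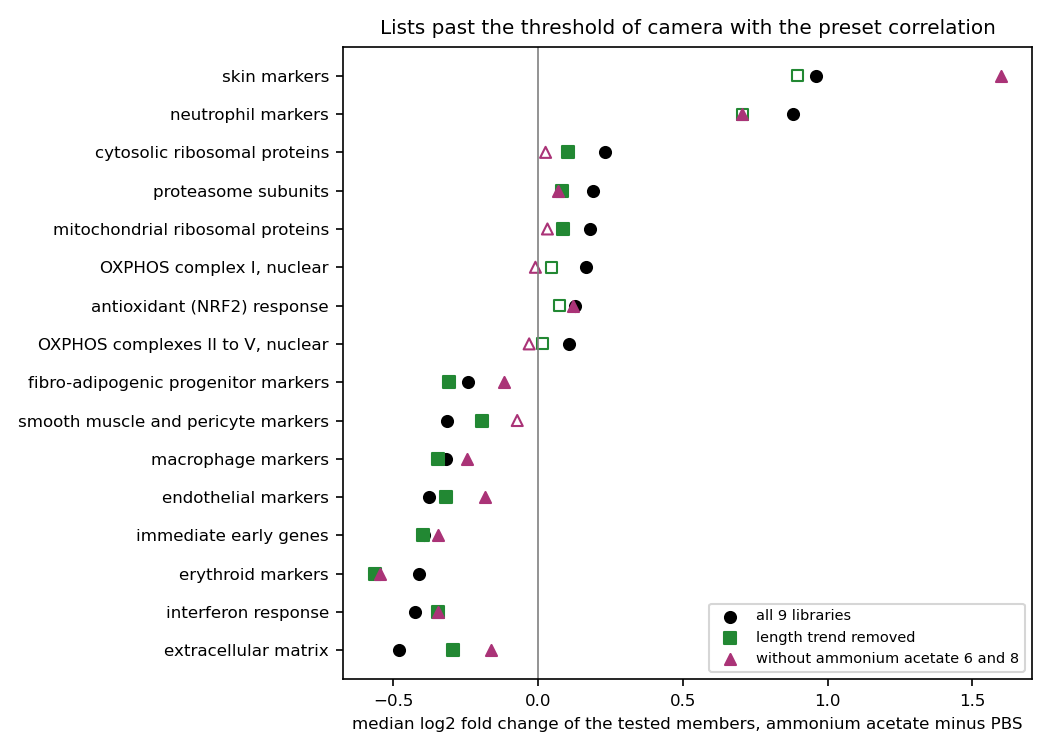
Median log2 fold change (horizontal axis, ammonium acetate minus PBS) of the 16 lists past 0.05 by camera with the preset correlation. Circles use 9 libraries, squares the values with each library's gene length trend removed, triangles the 7 libraries without ammonium acetate 6 and 8, and open symbols do not pass 0.05. None of the 16 passes with an estimated correlation.

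The lists closest to the question of the study did not pass in the main fit with the preset correlation. Ammonia and glutamine handling had 7 of 18 members higher (median -0.07, adjusted p = 0.947), although Gpt2, the mitochondrial alanine aminotransferase, measured 91.6 ± 9.66 FPKM in PBS and 130 ± 31.4 in ammonium acetate. The ATF4 target list of the integrated stress response had 11 of 28 higher (median -0.04, mean 0.02, adjusted p = 0.561), with the serine synthesis gene Psph at 3.56 ± 0.414 and 4.96 ± 1.36. NF-kB targets had 4 of 11 higher (median -0.05, adjusted p = 0.947), with Relb at 3.24 ± 0.684 and 4.53 ± 1.32. Myostatin and TGF-beta signalling had 12 of 17 lower (median -0.12, adjusted p = 0.245), with the TGF-beta binding protein Ltbp4 at 25.7 ± 2.71 and 16.7 ± 6.78. The log2 fold change of Ltbp4 was -0.70, and -0.25 without ammonium acetate 6 and 8. Ubiquitin ligases of atrophy and FoxO genes were lower in 12 of 18 (median -0.15, adjusted p = 0.192), with the transcription factor Foxo3 at 4.64 ± 0.974 and 3.26 ± 0.706. Autophagy and lysosome genes were higher in 14 of 25 (median 0.05, adjusted p = 0.249). Senescence and p53 targets were lower in 13 of 19 (median -0.06, adjusted p = 0.947), with the cell cycle inhibitor Cdkn2b at 1.30 ± 0.190 and 2.07 ± 0.675. Genes of mitochondrial biogenesis, sirtuins and dynamics were lower in 12 of 20 (median -0.04, adjusted p = 0.534). Mitochondrially encoded mRNAs were lower in 9 of 13 (median -0.20, adjusted p = 0.146), with mt-Nd5 at 6284 ± 619 and 4762 ± 826. This list passed with the gene length trend removed (median -0.32, adjusted p = 0.000117, p = 0.10 with an estimated correlation) and without ammonium acetate 6 and 8 (-0.17, adjusted p = 0.0111, p = 0.316 with an estimated correlation). It also passed without PBS 7 (-0.30), PBS 8 (-0.19), ammonium acetate 6 (-0.18) or ammonium acetate 7 (-0.28), each with the preset correlation. With 9 libraries it passed at a mean FPKM of at least 2 (adjusted p = 0.0299), rescaled to TPM (0.0494), with quantile normalization (0.00363), without a variance trend (0.0442), with library weights (0.0175) and with voom (0.0374), and the ubiquitin ligase list passed with quantile normalization (0.0313). Without ammonium acetate 6 and 8 the medians of the other 8 lists were -0.04 for ammonia handling, 0.05 for ATF4 targets, 0.02 for NF-kB targets, -0.02 for TGF-beta signalling, -0.02 for ubiquitin ligases, 0.02 for autophagy, 0.02 for senescence and -0.03 for mitochondrial biogenesis, and none of these 8 passed. The log2 fold change was then 0.16 for Psph (0.40 with all libraries), -0.26 for Foxo3 (-0.45) and -0.23 for mt-Nd5 (-0.41). It moved less for Gpt2 (0.37, from 0.48), Relb (0.32, from 0.41) and Cdkn2b (0.44, from 0.48). The values of mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l are uncertain, since at least 98.0% of their sequence is shared with annotated nuclear genes. The 4 members with a higher mean in ammonium acetate were mt-Nd3, mt-Co3, mt-Atp6 and mt-Atp8. They belong to the 6 members listed at 183 FPKM or less, of which mt-Co2 and mt-Nd4l had lower means. The 7 members listed at 4468 FPKM or more all had lower means. None of the members of these 9 lists passed in the main fit, over all genes or adjusted over the list alone.

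The remaining 20 lists gave no call in the main fit. Median log2 fold changes were 0.11 for glycolysis and glycogen (adjusted p = 0.0647), 0.25 for fast fibre genes (0.124), 0.07 for denervation and neuromuscular junction (0.256), 0.03 for endoplasmic reticulum chaperones (0.492) and 0.09 for brown adipocyte markers (0.749). They were -0.50 for adipocyte markers (adjusted p = 0.0504), -0.17 for fatty acid oxidation (0.124), -0.31 for Schwann cell markers (0.137), -0.53 for tendon markers (0.137) and -0.08 for sex-linked genes (0.442). They were -0.01 for the tricarboxylic acid cycle (0.737), -0.06 for the circadian clock (0.737), -0.12 for glucocorticoid targets (0.737) and -0.03 for calcium handling (0.816). In hypoxia targets (median -0.02, adjusted p = 0.816), heat shock genes (-0.02, 0.757) and satellite cell genes (-0.07, 0.947), as in the ATF4 targets, the median was negative and camera's direction positive. In slow fibre genes (0.10, 0.584) and translation control (0.03, 0.59) the median was positive and the mean negative. Some of these lists passed with the preset correlation in other settings. With the gene length trend removed the adipocyte (median -0.63, adjusted p = 0.00348) and fatty acid oxidation (-0.20, adjusted p = 0.0132) lists passed, and adipocyte markers also with the GC content trend removed (-0.46, adjusted p = 0.0462). Without ammonium acetate 6 and 8 glycolysis passed (0.09, adjusted p = 0.0161). With 1 library left out, adipocyte markers passed without PBS 4 (-0.75), 5 (-0.52) or 8 (-0.59) and ammonium acetate 5 (-0.63), 6 (-0.35) or 7 (-0.64), fatty acid oxidation without PBS 7 (-0.31) or ammonium acetate 7 (-0.40), and Schwann cell markers without PBS 7 (-0.52) or ammonium acetate 7 (-0.51). Glycolysis passed without PBS 4 (0.14), PBS 7 (0.19), ammonium acetate 7 (0.15) or 8 (0.13), fast fibre genes without PBS 4 (0.27), PBS 7 (0.27) or ammonium acetate 7 (0.31), and tendon markers without PBS 4 (-1.0) or PBS 7 (-0.77). With 9 libraries and no trend removed, adipocyte markers passed with a pseudocount of 0.1 (adjusted p = 0.0463), at a mean FPKM of at least 2 (0.0447), with median-ratio scaling (0.0437), quantile normalization (0.0124) and voom (0.0374). They also passed with the replicate number as a block (0.000863), where ammonium acetate 6, without a PBS partner, adds nothing to the fold changes. Fatty acid oxidation passed at a mean FPKM of at least 2 (0.0370), with quantile normalization (0.00266) and with library weights (0.000264). Tendon markers passed with library weights (0.0233) and with the block (0.0399), the latter again without a contribution of ammonium acetate 6. The tricarboxylic acid cycle passed with quantile normalization (0.00548). Glycolysis passed rescaled to TPM (0.0345), without a variance trend (0.0288), with robust moderation (0.0477), library weights (0.000493) and voom (0.0328), and fast fibre genes rescaled to TPM (0.0345), without a variance trend (0.0441), with library weights (0.00504) and with voom (0.0374). With an estimated correlation no list passed with the length trend removed or without ammonium acetate 6 and 8. Only 1 lymphocyte marker was tested, so that list had no test.

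The composition of the muscle pieces did not differ past the threshold in any of 18 measures. The erythroid genes took 0.0404% ± 0.00446 of summed FPKM in PBS (SD, n = 4) and 0.0270% ± 0.00437 in ammonium acetate (SD, n = 5). That difference had an exact two-sided permutation p of 0.00794, the smallest the design allows, and an adjusted p of 0.143. A measure that differed alone could therefore not pass over 18 measures, so the absence of a call is weak evidence of equal composition. Mitochondrially encoded mRNAs took 20.3% ± 1.93 and 16.7% ± 2.14 (exact permutation p = 0.0397, adjusted p = 0.238). Fast fibre genes, the main contractile genes of this muscle, had mean log2 values of 11.99 ± 0.151 and 12.06 ± 0.125, and slow fibre genes 6.22 ± 0.637 and 6.21 ± 0.545.

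Libraries 6 and 8 of ammonium acetate stood apart from the other 7. On the first principal component, 43.5% of the variance, they scored 38.8 and 28, where the others lay between -27.9 and 4.50. Their log2 values fell with gene length, by slopes of -0.17 and -0.16 per doubling, where the others had slopes between -0.01 and 0.12. They also held 312 and 568 genes with a single read against 891 to 1232 in the others. Between the groups, the median log2 fold change went from 0.14 in the shortest class of genes to -0.21 in the longest, of 5 classes of equal size. The difference in slope between the groups did not pass (exact permutation p = 0.127, adjusted p = 0.476 over 6 technical measures).

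**Figure D4:**
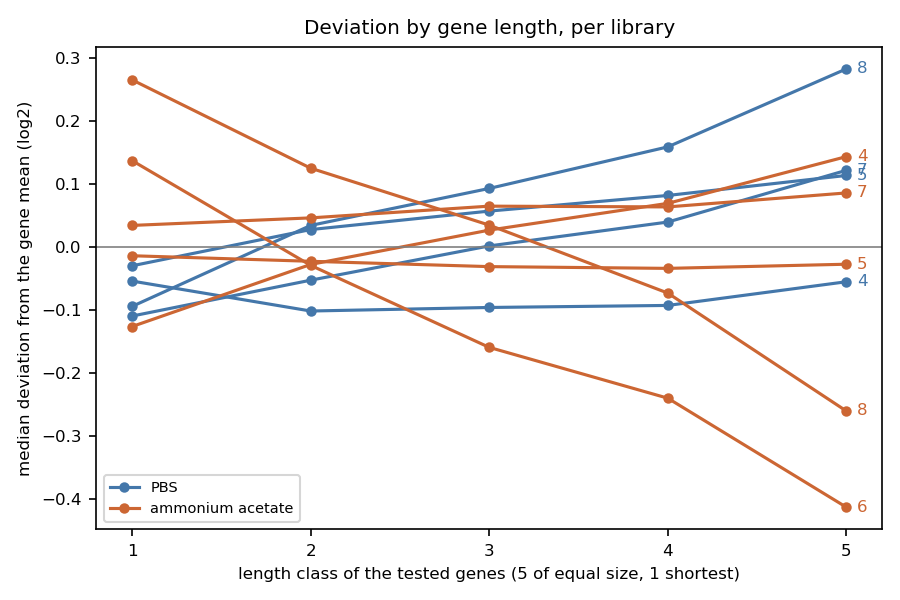
Median deviation of log2 values from the gene mean (vertical axis) by length class of the 11337 tested genes (horizontal axis, 5 classes of equal size, 1 shortest), 1 line per library, with the library's number at its right end. Ammonium acetate 6 and 8 reached -0.41 and -0.26 in the longest class, and the other libraries lay between -0.06 and 0.28.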

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

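The tests of the stromal share, of residual blood and of the length trend in the higher and the lower lists apart were chosen only after the results they measure had been seen. The tests of the length and GC trends over the 16 lists, of libraries 6 and 8 and of PBS 8 were also prompted by the data, but their outcomes were set down before the values were computed. The medians and SD of lists before and after a trend was removed were added after the calls were known, and so was the rule that splits decide nothing about a count of 0. A library counted as far from its group when its gap to the nearest other library took most of the group's range (Dixon's criterion). This held in 16 of 256 groups examined, 6.25%, where chance gives about 1 in 20.

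Skin genes stood out in ammonium acetate 5, with Krt5 at 19.32 FPKM (others up to 0.0745), Krt10 at 16.09 (others up to 0.867), Lor at 9.087 (others up to 0.321) and a mean log2 value of the skin list of 3.611. In PBS 7, Krt5 stood at 0.01093 FPKM, a single read, and at 0 in the other PBS libraries. Art5 was high in ammonium acetate 5 at 9.554 FPKM against 6.59 to 7.40 in the others. In ammonium acetate 8, Relb stood at 6.823 FPKM and Psmc4 at 51.3. In PBS 4, Csf1r was low at 1.818 FPKM against 4.08 to 4.51, the mean log2 value of the macrophage list was low at 1.438, and the 10 genes of highest mean took 34.62% of summed FPKM. Alas2 stood at 2.70 FPKM in PBS 5, and mitochondrially encoded mRNAs took 17.4% of summed FPKM in PBS 7 against 20.97% to 21.6%.

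PBS 8 was high in Gbp2 at 21.45 FPKM (others 3.51 to 5.28), Isg15 at 4.029 (others 1.48 to 1.82) and Wars at 31.91 (others 15.8 to 18.0), 3 genes that interferon induces. Without PBS 8 the interferon list kept 45.83% of its median log2 fold change, less than 50%, with an adjusted p of 0.00874. That PBS library may therefore account for much of the difference but not for all of it. Whether the remainder comes from ammonium acetate stays open, since no list passed with an estimated correlation.

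Of the 16 lists past the preset-correlation threshold, 8 were higher and 8 lower, with short housekeeping genes among the higher and stromal genes among the lower. Removing each library's GC trend kept 14 of the 16 calls, which argues against GC content as their common cause, and smooth muscle (median -0.31, SD over its genes 0.321, to -0.26, SD 0.325) and skin (0.96, SD 0.125, to 0.99, SD 0.141) lost theirs with medians little moved. Removing the length trend kept 11 and leaving out ammonium acetate 6 and 8 also kept 11, and the share of the calls that these 2 libraries account for cannot be told apart from the rest. A lower share of stromal cells stays open too, since the group difference of the ribosomal list exceeded that of the fast fibre list by 0.1481 (exact permutation p = 0.333). Chance was not excluded. Of 100 splits of the libraries, the real one included, 33 called at least 16 lists, and the highest other split called 23.

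The 8 lower lists did not all follow gene length, since erythroid and macrophage genes are short (median length 703 and 1355 bases) and lay lower. With the length trend removed, 8 of the 8 kept the call with the preset correlation, which argues against a gene length trend as the whole cause of the observed medians. Chance was not excluded by these calls. With the trend removed, 42 of 100 splits, the real one included, called at least 14 lists, the count of the real grouping. The highest other called 24. The medians came to -0.34 from -0.32 for macrophage, -0.31 from -0.24 for progenitor, -0.56 from -0.41 for erythroid, -0.40 from -0.39 for immediate early, -0.35 from -0.42 for interferon and -0.32 from -0.38 for endothelial genes. The trend may account for part of the matrix (-0.48 to -0.29) and smooth muscle (-0.31 to -0.19) differences.

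Of the 8 higher lists, 3 kept the call with the length trend removed, with smaller medians in cytosolic ribosomal (0.23 to 0.10), mitochondrial ribosomal (0.18 to 0.09) and proteasome (0.19 to 0.08) genes. The medians also shrank in complex I (0.17, SD 0.0943, to 0.05, SD 0.103), complexes II to V (0.11, SD 0.105, to 0.02, SD 0.0943) and antioxidant genes (0.13, SD 0.190, to 0.08, SD 0.177), which lost the call. Neutrophil (0.88, SD 0.881, to 0.71, SD 0.767) and skin (0.96 to 0.90, SD 0.120) markers lost it with medians little moved. Whether a gene length trend accounts for the higher lists therefore stays open.

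With 0 genes called, a comparison of splits says nothing about the count of genes: all 100 splits must call as many, and the highest other called 13. Chance was not excluded for the 972 genes at an unadjusted p under 0.05, since 21 of 100 splits, the real one included, gave as many. The highest other split gave 3724. Such a split points to a structure of the samples. The 47 splits that kept ammonium acetate 6 and 8 in the same group gave a median of 504 such genes and the 53 others 187, but the median count of lists was 14 in both, and the difference was not tested.

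Erythroid genes were lower in ammonium acetate. The length trend does not account for this, since 128.8% of the difference was left once it was removed (exact permutation p = 0.0159). Less blood left in the muscle stays open: neutrophil genes, which come with blood, differed by 0.6313 in the opposite direction, but with an exact permutation p of 0.0873 and on few reads. An effect of ammonium acetate on red cell genes is equally untested beyond this comparison.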

How the results depend on the processing

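The alternatives with ammonium acetate 6 and 8 left out, the length and GC trends removed and voom were chosen after seeing the data. The count of genes was 0 under all 26 alternatives, with 256 to 1730 genes at an unadjusted p under 0.05 across other fits than the main one. The alternatives that only changed the threshold were bound to give 0, since the smallest adjusted p of the main fit was 0.527. The count of lists was 13 to 21 under 24 alternatives (14 to 21 with 1 library left out, 13 without ammonium acetate 6 and 8, 14 with the length trend removed). These kept 11 to 16 of the 16 calls in the same direction. Calls were also gained, since 9 of the 28 lists without a call passed in at least 1 alternative, adipocyte markers in 14, mitochondrially encoded mRNAs in 12, glycolysis in 10, fast fibre genes in 7, fatty acid oxidation in 6, tendon in 4 and Schwann cell markers in 2. The tricarboxylic acid cycle (adjusted p = 0.00548) and the ubiquitin ligases of atrophy (adjusted p = 0.0313) passed with quantile normalization alone. The count was 0 with an estimated correlation, which in the 16 lists lay between 0.0876 and 0.995 in place of 0.01. Only the handling of the correlation changed there, so the 16 calls depend on the preset value. The count was also 0 by fry, with the cause not tested. The list of respiratory complexes II to V turned to a median of -0.0302 without ammonium acetate 6 and 8 (adjusted p = 0.313); the cause was not tested. Quantile normalization ended the calls of complex I (adjusted p = 0.158), complexes II to V (0.946), antioxidant (0.142) and skin (0.0651) genes. Library weights ended those of complex I (0.171), complexes II to V (0.892) and smooth muscle (0.678). The smooth muscle list also failed by a small margin with no filter, 2 other scalings or no trend (adjusted p from 0.0501 to 0.0565), the skin list with median-ratio scaling (0.0940) and the interferon list at a mean FPKM of at least 2 (0.230). Of the 16 called lists, 7 lost the call without some single library. The count of composition measures was 0 in every alternative run, but this is weak evidence of stability. With the block no exact p can fall below 0.125, so that 0 was fixed in advance. Without ammonium acetate 6 and 8 none can fall below 0.0286, and with all 9 libraries none below 0.00794. With 1 library left out fewer splits remain. In all of these a measure that differed alone could not pass over 18 measures. The 20 genes of smallest p kept their sign in every alternative run. They were picked by p from the same libraries, which makes a stable sign likely whatever the cause. Of the 107 named genes, 10 did not keep their sign, 9 of them among the 16 fixed genes. Sign changes of results that pass in neither setting were not counted as reversals. Scaling moved the median of all log2 fold changes by at most 0.0637.

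The replicate numbers 4, 5, 7 and 8 are shared by both groups. Once each group's mean of each gene was taken off, same-numbered libraries correlated at -0.28, -0.07, -0.34 and -0.28. This gave no sign of a shared origin, but so few pairs cannot exclude a shared cage or day. With the number as a block there were 0 genes (260 unadjusted) and 17 lists (15 of the 16, without complexes II to V, adjusted p = 0.0898). The count of 0 composition measures with the block tells nothing, since no exact permutation p could fall below 0.125 there. No ammonium acetate library correlated best with its own number. Depth limits the genes of low FPKM, such as S100a8 on 3 to 32 reads. With ammonium acetate 5 left out the skin list had too few tested genes and gave no value.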

Other observations

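The lists in this part were drawn up after the leading genes had been seen, and the giant genes with the length trend in mind, so they are not independent evidence. All 18 giant sarcomere and cytoskeleton genes tested had lower values in ammonium acetate, with a median log2 fold change of -0.63 (camera adjusted p = 6.48e-08, p = 0.134 with an estimated correlation). Titin (Ttn) measured 56.0 ± 8.40 FPKM in PBS and 35.5 ± 20.46 in ammonium acetate, nebulin (Neb) 190 ± 26.8 and 126 ± 53.8, and dystrophin (Dmd) 8.72 ± 1.18 and 5.32 ± 2.36. With the length trend removed the median was -0.20 (adjusted p = 0.0037). Among 12 secreted muscle factors 3 were higher and 9 lower, and the list did not pass (median -0.19, adjusted p = 0.483). Il15 measured 3.72 ± 1.25 and 2.0 ± 0.896 FPKM against the higher values of Ostn. Spliceosome genes did not pass (median 0.06, mean -0.00131, adjusted p = 0.442).

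The outcome that each of the next 3 hypotheses required was set down before its test was run, but the hypotheses came from the data. Because Aurka was among the leading genes, cell division genes may as a group be higher in ammonium acetate. The median of 10 cell cycle genes was -0.0421 (p = 0.425 with an estimated correlation) and 7 were lower. Of these, Aurka, Tpx2 and Mad2l1 act in mitosis and the others, the Mcm genes, Pcna and Rrm1, in DNA replication. The list therefore says little about mitosis alone. A median at or below 0 was the outcome set down beforehand as speaking against the hypothesis, and it was met. The mean of the 10 genes, raised by Aurka itself, was 0.0438 and camera's direction was up, so the list does not settle the question. Because Neat1 was near the top of the lower genes (2.38 ± 0.841 and 1.15 ± 0.401 FPKM), nuclear-retained RNAs may be lower. The median of 4 was -0.3842 (p = 0.313 with an estimated correlation), with Malat1 at 11.9 ± 3.19 and 7.53 ± 3.22. The other members, Gas5 (log2 fold change 0.14) and Snhg1 (-0.07), are host genes of small nucleolar RNAs rather than clear nuclear-retained RNAs. The list is therefore a weak test. Neat1 itself is in the list and the median shrank to -0.17 with the length trend removed, so this stays open.

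Of the 13 mitochondrially encoded mRNAs, 6 (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, from position 7013 to 10173 of the mitochondrial genome) were listed at 0.815 to 183 FPKM. The other 7 stood at 4468 to 28119. It was proposed that reads also matching a nuclear copy were not counted, which required each low mRNA to share at least 50% of its 50-mers with a transcript from outside the mitochondrial genome and each high mRNA at most 10%. The low and high mRNAs were told apart by their values. The requirement failed, since mt-Atp8 shared 0% and the high mRNAs mt-Nd4 and mt-Co1 shared 62.23% and 51.14%. Sharing of a part leaves the other reads of mt-Nd4 and mt-Co1 countable, so their high values do not decide the proposal. The other 5 low mRNAs shared 98.0% to 100%, most with annotated copies on chromosome 1 between 24612407 and 24615565. The search covered annotated transcripts only, and none shared sequence with mt-Atp8, so a copy without annotation was not examined. In the mitochondrial genome mt-Atp8 lies between mt-Co2 and mt-Atp6. On chromosome 1 the copy of mt-Atp6 ended at 24614651 and that of mt-Co2 began at 24614885. A copy in between would have been missed without annotation, so the 0% of mt-Atp8 does not decide the proposal either. Shared reads may still lower the 5 low mRNAs other than mt-Atp8, and their values are uncertain.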
